A study of Mus musculus with 15 samples.

How the data were processed

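Poly(A) RNA from mouse liver was sequenced in 15 libraries, which the labels place in 3 groups: 4 libraries labelled TdTomato, 6 labelled LATS KO and 5 labelled Yap OE. They are called TdTomato (the controls), LATS_KO and YAP_OE here. Per the labels' protocols, RNA was column-purified, poly(A)-selected and made into directional libraries that were read on a NovaSeq instrument. The extraction text of the labels describes mice of another design, which does not match these 15 libraries, so no animal, age, diet or time point was taken from it. No label says that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which could be technical.

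The authors deposited raw gene counts for each library, as whole numbers in the layout that STAR writes, with 1 column without strand and 1 for each strand. Per the submitters' processing notes, FastQC, Trimmomatic and STAR were used with the mm10 genome, without versions or settings. The column for reverse-stranded kits was used, because the forward column held only 0.966% to 1.99% of the strand-assigned counts. The files hold 24411 genes by symbol. Lines for unmapped, multiply mapped, unassigned and ambiguous reads named no gene and were kept out of library sizes and tests, and held between 14.2% and 92.5% of all reads of a library. Reads mapping to several places were not counted per gene, so near-identical families such as the Mup, Cyp2d, Ugt2b, Serpina3, Orm, Saa, H2 and Rnaset2 genes are uncertain. Coordinates were taken from the GENCODE M21 annotation of GRCm38, the assembly also called mm10.

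Counts assigned to genes ranged from 6166680 to 28225400 per library. From the deposited counts, values scaled to library size (CPM) were computed with TMM-scaled library sizes. Genes were kept with the default filterByExpr rule, which left 13055. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit with robust = TRUE, glmQLFTest) in R 4.3.3. A single fit held all 15 libraries with the group as the only term, leaving 12 residual degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are given with their standard errors (SE), computed as the size of the change divided by the square root of the test statistic. A fold against a group with 0 counts in all libraries was computed against a floor of 3 counts over the whole group and is given as a lower bound. With 1 to 3 counts in a group, the ratio of CPM is given with its exact 95% interval. These bounds and intervals cover counting error only.

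The lists comprised 28 pathway lists and 17 lists of cell type markers, 45 in all. Of the 702 symbols, 2 were matched through an older symbol (Ccn1 as Cyr61, Ccn2 as Ctgf) and 4 had no entry. The 37 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over all lists and comparisons. Camera was repeated with an estimated correlation, and fry was run as a test that does not compare a list with other genes. Counts of list members past the threshold are given over all genes and, in brackets, when adjusted over the list alone and in the fit without TdTomato 1 and LATS_KO 3, called the reduced fit, which was added after seeing the data. The results of 2 genes that the fixed rule would name are not reported here.

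The lists, the comparisons, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the manipulated genes and the YAP paralog, 17 further genes chosen for the study's subject, up to 3 members of each list with the smallest adjusted p, and the 5 largest rises and falls of each comparison among genes with a mean CPM of at least 5 and no overlap between groups. Riken, Gm-numbered, mitochondrial, sex-linked, haemoglobin, immunoglobulin and T cell receptor genes were passed over in that last part. For a list without a member past the threshold the rule asked for its most abundant member, and only the counts are given here instead.

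The alternatives were RLE factors, DESeq2 1.42.0, limma voom with quality weights, other filters on low counts, the unstranded column, a fit of only the groups compared, the replicate number as a block, the first surrogate variable of sva 3.50.0, and leaving out each library in turn. A fit without TdTomato 1 and LATS_KO 3, in which over 70% of the reads were unmapped, was added after seeing the data. A sex term was planned only for libraries that differed in sex. Xist reached at most 0.155 CPM and Ddx3y at least 46.5 CPM in all 15 libraries, so it was not run.

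No pair of replicates differed only by sampling noise. The procedure was tested on simulated counts in which 200 of the 13055 genes were changed. For LATS_KO against TdTomato it recovered 6.06% of the 2-fold, 53.7% of the 4-fold and 65.7% of the 8-fold changes, with 1 false call. For YAP_OE against TdTomato these shares were 0%, 43.3% and 68.7%, with 2 false calls, and for YAP_OE against LATS_KO 6.06%, 46.3% and 76.1%, with 1 false call. Changes of 2-fold were therefore mostly not detectable at the simulated spread. A fit of the real TdTomato and LATS_KO libraries alone called 1 gene, against 1438 with YAP_OE in the fit. The simulated shares and false calls therefore do not show how reliable the calls of that comparison are.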

Results

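Gene expression was measured by RNA sequencing of mouse liver in 4 control libraries (TdTomato), 6 libraries labelled as lacking LATS (LATS_KO) and 5 labelled as overexpressing Yap (YAP_OE). LATS1 and LATS2 are kinases of the Hippo pathway that restrain the transcriptional coactivator YAP, and the title of the study concerns inflammatory monocytes and YAP-driven proliferation. Depth ranged from 6166680 to 28225400 counts per library. In TdTomato 1 and LATS_KO 3, 78.5% and 89.9% of the reads were unmapped, against 2.53% to 16.7% in the other 13 libraries. These libraries detected 8501 and 9710 genes, against at least 13372 in each of the others. The share of mapped reads outside annotated genes was 17.2% to 25.8% in LATS_KO 3, 4, 5 and 6, and 6.57% and 7.05% in LATS_KO 2 and 1.

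**Figure D1:**
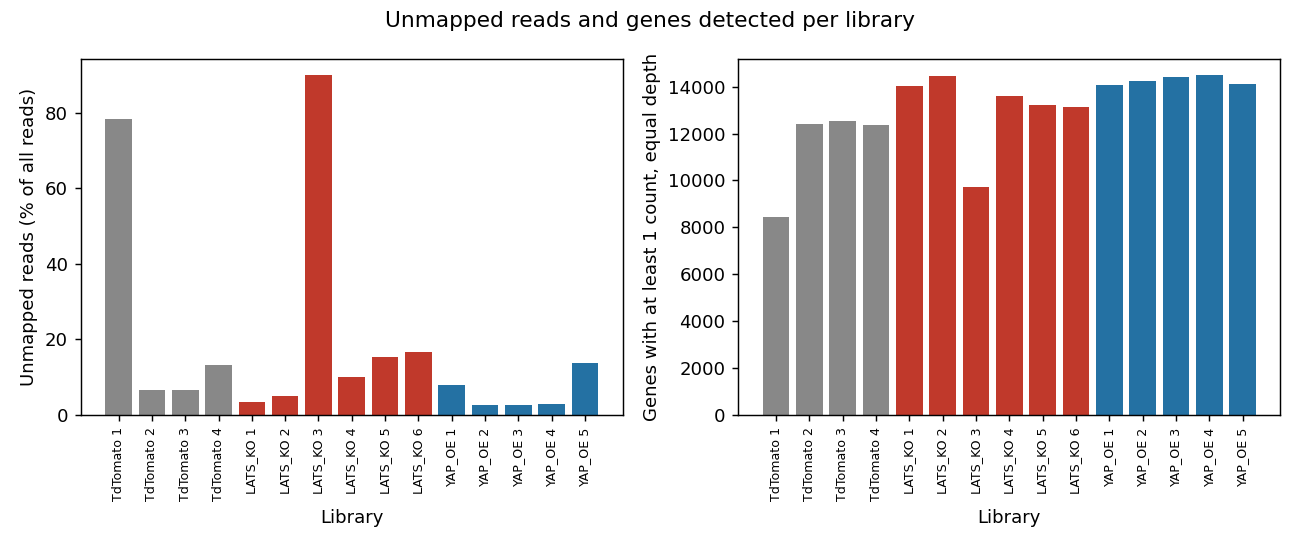
Unmapped reads as a percentage of all reads (left) and genes with at least 1 count after thinning each library to 6166680 counts (right), 1 bar per library, with TdTomato in grey, LATS_KO in red and YAP_OE in blue. TdTomato 1 and LATS_KO 3 had the most unmapped reads, 78.5% and 89.9%, and the fewest genes, 8427 and 9710.

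The manipulated genes were examined first. Lats1 (chromosome 10, 7681214 to 7716460, mm10) was at 0, 44.5, 46.0 and 28.7 CPM in TdTomato 1 to 4, and at 14.5, 10.5, 0, 27.4, 18.1 and 22.3 CPM in LATS_KO 1 to 6. Its log2 fold change of −0.94 ± 1.00 (SE) in LATS_KO did not pass the test (adjusted p = 0.62, edgeR). Without TdTomato 1 and LATS_KO 3, a fit added after seeing the data, it was −1.10 (adjusted p = 0.025). Lats2 (chromosome 14, 57689662 to 57758388) was at 0, 19.6, 19.1 and 17.4 CPM in TdTomato 1 to 4, at 29.2, 41.0, 7.67, 16.9, 17.3 and 14.0 CPM in LATS_KO 1 to 6 and at 62.2, 61.1, 53.8, 54.8 and 48.8 CPM in YAP_OE 1 to 5. Neither difference from TdTomato passed the test (adjusted p = 0.70 and 0.078), nor did that of Lats1 in YAP_OE (0.043 ± 1.06, adjusted p = 0.98), with 30.9, 36.2, 39.8, 26.6 and 20.1 CPM in YAP_OE 1 to 5. Lats2 in YAP_OE passed it without TdTomato 1 (1.58, adjusted p = 0.013), without both TdTomato 1 and LATS_KO 3 (1.58, adjusted p = 0.0022), and with RLE factors, DESeq2, voom and a surrogate variable. Counts over a whole gene include exons outside a deleted part, so these values do not check the deletion.

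Yap1 (chromosome 9, 7931999 to 8004596) was at 94.9, 115, 103 and 103 CPM in TdTomato 1 to 4, at 212, 184, 146, 196 and 181 CPM in YAP_OE 1 to 5, and at 86.4, 66.0, 72.1, 86.3, 81.1 and 76.6 CPM in LATS_KO 1 to 6. It rose in YAP_OE by 0.82 ± 0.17 on the log2 scale (adjusted p = 0.0043) and did not pass the test in LATS_KO (−0.41 ± 0.16, adjusted p = 0.11), where DESeq2 (−0.35, adjusted p = 0.016) and voom (−0.41, adjusted p = 0.013) called it lower. A transgene with another sequence would not be fully counted here. Wwtr1 (chromosome 3, 57455649 to 57575910), which encodes the YAP paralog TAZ, was at 5.11, 15.9, 18.2 and 9.58 CPM in TdTomato 1 to 4, at 49.7, 74.0, 103, 22.3, 17.7 and 16 CPM in LATS_KO 1 to 6 and at 67.6, 55.5, 55.8, 61.3 and 52.6 CPM in YAP_OE 1 to 5. It rose in LATS_KO by 1.95 ± 0.52 (adjusted p = 0.027) and in YAP_OE by 2.26 ± 0.54 (adjusted p = 0.0082). The rise in LATS_KO no longer passed the test without TdTomato 1, TdTomato 2, TdTomato 4 or LATS_KO 2 (adjusted p = 0.068, 0.061, 0.085 and 0.059), nor without both TdTomato 1 and LATS_KO 3 (1.31, adjusted p = 0.071).

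The first comparison asked how livers labelled LATS_KO differed from controls. Higher in LATS_KO were 13 of 20 YAP target genes, 24 of 24 mitotic genes and 10 of 15 macrophage genes, and 10 of 20 cholesterol synthesis genes were lower. Camera called these 4 lists, and no call held with an estimated correlation (adjusted p = 0.31, 0.31, 0.31 and 0.31). Ctgf, a matricellular YAP target (chromosome 10, 24595442 to 24598683), was at 1263 ± 1395 CPM (SD, n = 6) against 0.216 ± 0.238 CPM (n = 4), and Cyr61 (chromosome 3, 145646976 to 145649981) at 453 ± 405 against 20.2 ± 15.3 CPM. The proliferation marker Mki67 was at 72.8 ± 76.5 against 3.87 ± 2.69 CPM, and Csf1r, the macrophage growth factor receptor, at 108 ± 94.1 against 1.49 ± 1.33 CPM. The 6 libraries were far from uniform. Ctgf was at 1811, 2485, 3136, 82.7, 41.7 and 20.6 CPM in LATS_KO 1 to 6, each above the highest control at 0.556 CPM. Leaving out 1 library ended the call for Cyr61 (TdTomato 2 or 4, adjusted p = 0.054 and 0.066).

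In all, 1438 of 13055 genes passed the test in edgeR, 1311 higher and 127 lower. This number rests on pooling the spread with YAP_OE. A fit of the TdTomato and LATS_KO libraries alone called 1 gene, Cebpe (adjusted p = 0.049), with 2013 genes at an unadjusted p under 0.05, and lost 83 of the 89 calls of genes named in this comparison. Without TdTomato 2, TdTomato 3, TdTomato 4 or LATS_KO 2, the count was 588, 765, 625 and 897. Without both TdTomato 1 and LATS_KO 3 it was 2245, of which 1245 were shared with the 1438 in the same direction. Of the 89 genes named in this comparison that passed the test, 54 passed it without each of the 15 libraries in turn. DESeq2 called 2535 genes higher and 359 lower, and voom 2105 and 1396. For the named genes with a call that was lost, the text gives the library left out and the adjusted p without it. Voom no longer called 10 of these genes, Wwtr1 (0.48, adjusted p = 0.15), Krt19 (2.57, adjusted p = 0.13), Sox9 (0.34, adjusted p = 0.56), Afp (0.29, adjusted p = 0.88), Jag1 (1.82, adjusted p = 0.096), Eda2r (1.70, adjusted p = 0.18), Phgdh (3.78, adjusted p = 0.075), Psat1 (1.89, adjusted p = 0.20), Fmo2 (1.87, adjusted p = 0.059) and Fbln2 (2.43, adjusted p = 0.18).

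Values in brackets are log2 fold changes with their SE, or ratios of CPM. The reduced fit is the one without TdTomato 1 and LATS_KO 3. Where leaving out 1 library moved a fold by over 1.5 times, the log2 fold change without it is given. Among YAP/TEAD targets, 13 of 20 members (17 over the list alone, 15 in the reduced fit) rose, with the smallest p for Ctgf, Axl (7.05 ± 1.03) and Myof (ratio 1462, 95% interval 404 to 12073). Ankrd1, another target, had a ratio of 2017 (95% interval 362 to 79699.9) from 1 control count. The ratio was 535 (Myof) without LATS_KO 2. Cyr61 rose by 4.49 ± 1.12. All 24 G2/M and mitosis genes rose (24 over the list alone, 24 in the reduced fit), among them Kif23 (6.27 ± 1.04), Ccnb2 (5.21 ± 0.92) and Foxm1 (5.22 ± 0.96), and Mki67 rose by 4.24 ± 0.89. DNA replication genes rose in 14 of 24 members (19 over the list alone, 17 in the reduced fit), such as Uhrf1 (6.03 ± 1.17), Cdc6 (ratio 90.8, 95% interval 30.9 to 442) and Rrm2 (3.69 ± 0.76). Camera placed the mitosis and replication lists higher than other genes (adjusted p = 2.8e-20 and 3.9e-08), and each call was lost with an estimated correlation (adjusted p = 0.31 and 0.31). Hippo pathway components rose in 6 of 22 members (8 and 1 lower over the list alone, 3 and 3 lower in the reduced fit), including the TEAD factors Tead4 (at least 211-fold higher) and Tead2 (5.40 ± 1.21). The lower bound was 128 (Tead4) without LATS_KO 2. In the reduced fit camera gave the Hippo list an adjusted p of 0.84, against 0.18 with all libraries. Single libraries decided the call for Cyr61 (TdTomato 2 or 4, adjusted p = 0.054 and 0.066) and Tead2 (TdTomato 2 or 4, adjusted p = 0.051 and 0.0504). Log2 fold changes with 1 library left out were 6.99 for Uhrf1 without TdTomato 2, and 5.87 for Ccnb2 and 6.41 for Tead2 without TdTomato 3. With 1 left out, the log2 values were 7.77 for Axl without TdTomato 4, and 6.21 for Axl, 3.52 for Mki67 and 5.51 for Kif23 without LATS_KO 2. Tead2 had a log2 fold change of 4.65 without LATS_KO 3.

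Inflammatory monocyte markers rose in 9 of 10 members (9 over the list alone, 9 in the reduced fit), including Csf1r (6.16 ± 0.87), Fcgr1 (6.23 ± 1.08) and Ms4a6c (ratio 169, 95% interval 57.5 to 819). Ccr2, the receptor for monocyte chemoattractants, had a ratio of 172 (95% interval 58.5 to 833) from 3 control counts. Ly6c2 was too low to be tested, at 0.537 ± 0.622 CPM (SD, n = 6) against 0.137 ± 0.122 CPM (n = 4). Macrophage markers rose in 10 of 15 members (14 over the list alone, 12 in the reduced fit), with Lgals3 (ratio 573, 95% interval 196 to 2778), Ctss (6.12 ± 0.94) and Lyz2 (5.19 ± 0.90), and Adgre1 rose by 5.40 ± 1.25. Kupffer cell markers rose in 10 of 12 members (12 over the list alone, 12 in the reduced fit), with Clec4f (4.04 ± 0.87), Marco (6.88 ± 1.61) and Vsig4 (5.24 ± 1.23). Clec4f was at 6.98, 95.5, 8.67, 147, 126 and 53.4 CPM in LATS_KO 1 to 6, against at most 8.75 CPM in TdTomato. The mean log2 CPM of this list was 1.27, 4.88, −1.12, 4.42, 4.16 and 3.32 in LATS_KO 1 to 6, and −1.90 to 0.525 in TdTomato. LATS_KO 1 and 3 thus showed little or none of the rise. In these libraries Csf1r was at 94.1 and 88.1 CPM and Ctss at 16.3 and 26.1 CPM. Adgre1 was at 3.57 and 0 CPM there and Vsig4 at 3.35 and 0 CPM. In LATS_KO 4, Csf1r was at 79.8, Ctss at 64.4, Adgre1 at 24.9 and Vsig4 at 38.1 CPM, so Csf1r did not follow these macrophage markers across libraries. Neutrophil markers rose in 2 of 5 members (5 over the list alone, 3 in the reduced fit), Mmp9 (ratio 103, 95% interval 28.4 to 856) and Csf3r (3.74 ± 1.05). LATS_KO 2 weighed most on these ratios, with Lgals3 at 69.0 CPM against at most 20.9 CPM in the other 5. Without LATS_KO 2, the ratios were 68.6 (Ms4a6c), 52.9 (Ccr2), 209 (Lgals3) and 34.3 (Mmp9). With 1 library left out, the test was no longer passed by Adgre1 (TdTomato 2, adjusted p = 0.054) and Marco (TdTomato 2, adjusted p = 0.054). This also held for Vsig4 (TdTomato 2, adjusted p = 0.053) and Mmp9 (TdTomato 2, adjusted p = 0.054). The call also ended for Csf3r (TdTomato 1 to 4 or LATS_KO 1 or 2, adjusted p = 0.056 to 0.10). Values without 1 library were 7.04 for Fcgr1, 7.25 for Ctss, 6.07 for Lyz2, 6.12 for Adgre1, 8.10 for Marco and 5.96 for Vsig4 without TdTomato 4, and 5.55 for Csf1r, 5.38 for Ctss and 4.21 for Marco without LATS_KO 2.

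Some of the signals that recruit or activate these cells were also higher. The controls held few transcripts of cells other than hepatocytes, with Col1a1 at 0 CPM in TdTomato 1 to 4 and Adgre1 at most at 0.718 CPM. What the control tissue held therefore enters the folds of immune, matrix and other cell markers in both comparisons with TdTomato. It cannot be told apart from the group. Monocyte-recruiting chemokines and growth factors rose in 6 of 9 members (8 over the list alone, 5 in the reduced fit), with Ccl2 (ratio 817, 95% interval 226 to 6752), Ccl6 (6.15 ± 1.37) and Csf1 (5.10 ± 1.15). CXC chemokines rose in 2 of 8 members (4 and 1 lower over the list alone, 3 in the reduced fit), Cxcl2 (4.24 ± 1.11) and Cxcl13 (3.79 ± 1.03), and camera did not call this list (adjusted p = 0.53). Inflammatory cytokines and receptors rose in 6 of 12 members (8 over the list alone, 8 in the reduced fit), with Nlrp3 (ratio 70.3, 95% interval 19.2 to 583), Il1b (4.85 ± 1.13) and Il33 (3.89 ± 0.96). The ratio was 40.6 (Nlrp3) without LATS_KO 2. MHC class II and interferon-gamma genes rose in 8 of 16 members (9 over the list alone, 9 in the reduced fit), with H2-Eb1 (5.18 ± 0.92), Cd74 (4.90 ± 0.87) and H2-DMb1 (ratio 103, 95% interval 35.0 to 500.4). Type I interferon genes rose in 3 of 23 members (3 over the list alone, 7 in the reduced fit), Ifit2 (4.75 ± 0.89), Oas2 (ratio 70.8, 95% interval 19.4 to 588) and Oas3 (ratio 49.1, 95% interval 13.4 to 409). Leaving out 1 library ended the call for Cxcl2 (TdTomato 1 to 4, adjusted p = 0.0501, 0.076, 0.072 and 0.0504) and Cxcl13 (TdTomato 1 to 4 or LATS_KO 2, adjusted p = 0.0501 to 0.078). Single libraries likewise decided Il1b (TdTomato 2 or 4, adjusted p = 0.056 and 0.051) and Nlrp3 (TdTomato 2, adjusted p = 0.054). Also dependent on 1 library was the call for Il33 (TdTomato 2 or 3, adjusted p = 0.053 and 0.063) and Oas3 (TdTomato 1 to 4, adjusted p = 0.052, 0.079, 0.051 and 0.067). Leaving out single libraries gave log2 values of 4.59 for Cxcl13 and 5.45 for Ifit2 without TdTomato 2, and 7.85 for Ccl6 and 4.97 for Cxcl2 without TdTomato 4. Ccl6 had a log2 fold change of 4.49 without LATS_KO 2.

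Part of the bile duct, matrix and fetal liver genes were higher. Cholangiocyte markers rose in 8 of 14 members (10 over the list alone, 5 in the reduced fit), including Prom1 (7.25 ± 1.37), Sox4 (8.23 ± 1.60), Spp1 (5.51 ± 1.08), Krt19 (5.48 ± 1.41) and Sox9 (2.34 ± 0.70). Extracellular matrix genes rose in 13 of 26 members (20 and 1 lower over the list alone, 13 in the reduced fit), such as Timp2 (7.57 ± 1.37), Sparc (3.64 ± 0.68) and Thbs1 (ratio 658, 95% interval 225 to 3192). Col1a1 was at 0 counts in the controls and at least 49.7-fold higher in LATS_KO. Stellate cell and fibroblast markers rose in 2 of 16 members (3 over the list alone, 3 in the reduced fit), Fbln2 (7.35 ± 1.87) and Lum (ratio 28.8, 95% interval 4.94 to 1159). Sinusoidal endothelial markers rose in 6 of 18 members (12 over the list alone, 13 in the reduced fit), such as Flt4 (1.95 ± 0.48), Maf (0.80 ± 0.21) and Lyve1 (3.54 ± 0.95). Fetal liver and tumour-associated genes rose in 5 of 13 members (8 and 1 lower over the list alone, 4 in the reduced fit), with Gpc3 (ratio 44163, 95% interval 7926 to 1744350), Cd24a (ratio 139, 95% interval 47.3 to 675), Ly6d (5.33 ± 1.14) and Afp (4.13 ± 1.21). Camera placed the matrix and fetal lists higher than other genes (adjusted p = 6.0e-06 and 0.017), and both calls were lost with an estimated correlation (adjusted p = 0.37 and 0.38). Without LATS_KO 2, the ratios were 285 (Thbs1) and 21738 (Gpc3). The lower bound for Col1a1 was then 16.8. Without both TdTomato 1 and LATS_KO 3, Sox9 (2.36, adjusted p = 0.078) and Afp (3.05, adjusted p = 0.081) did not pass the test. Single libraries decided the call for Krt19 (TdTomato 2 or 3, adjusted p = 0.076 and 0.067) and Sox9 (TdTomato 1 to 4, LATS_KO 1 or 2 or YAP_OE 1 to 5, adjusted p = 0.057 to 0.11). This also held for Col1a1 (TdTomato 2, 3 or 4, adjusted p = 0.062, 0.054 and 0.062) and Fbln2 (TdTomato 1 to 4, adjusted p = 0.051, 0.068, 0.059 and 0.068). The call also ended for Lum (TdTomato 1, 2 or 4, LATS_KO 2 or 4 or YAP_OE 2, adjusted p = 0.053 to 0.11) and Flt4 (TdTomato 2, 3 or 4, adjusted p = 0.060, 0.062 and 0.063). Single libraries likewise decided Maf (TdTomato 2, 3 or 4 or LATS_KO 2, adjusted p = 0.089, 0.087, 0.076 and 0.053) and Lyve1 (TdTomato 2, 3 or 4 or LATS_KO 2, adjusted p = 0.086, 0.068, 0.077 and 0.054). Also dependent on 1 library was the call for Afp (TdTomato 1 to 4, LATS_KO 1, 2 or 3 or YAP_OE 1 to 5, adjusted p = 0.051 to 0.097). Log2 fold changes with 1 library left out were 8.98 for Sox4 and 8.30 for Timp2 without TdTomato 2, and 6.51 for Krt19 and 5.93 for Ly6d without TdTomato 4. With 1 left out, the log2 values were 1.53 for Sox9, 4.61 for Spp1 and 4.47 for Ly6d without LATS_KO 1, and 4.17 for Krt19 and 5.96 for Fbln2 without LATS_KO 2. Values without 1 library were 6.60 for Prom1, 7.36 for Sox4, 6.83 for Timp2 and 3.45 for Afp without LATS_KO 3.

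Notch pathway genes rose in 3 of 12 members with 1 lower (6 and 1 lower over the list alone, 5 and 1 lower in the reduced fit), with the ligands Jag2 (at least 8.09-fold higher) and Jag1 (5.52 ± 1.32) and the target Nrarp (3.98 ± 1.05). Among p53 targets 4 of 18 members (5 over the list alone, 4 in the reduced fit) rose, including Phlda3 (7.05 ± 1.21), Pmaip1 (ratio 112, 95% interval 19.9 to 4457) and Eda2r (4.36 ± 1.11). Among glycolysis genes 4 of 13 members (6 over the list alone, 5 in the reduced fit) rose, with Hk2 (ratio 84.5, 95% interval 28.7 to 411), Pkm (4.58 ± 0.83) and Slc16a3 (ratio 121, 95% interval 21.4 to 4792). Without LATS_KO 2, the ratios were 63.1 (Pmaip1), 43.4 (Hk2) and 67.1 (Slc16a3). ER stress and ATF4 targets moved both ways, 2 of 17 members higher and 4 lower (2 and 5 over the list alone, 2 and 4 in the reduced fit). The serine synthesis genes Phgdh (ratio 599, 95% interval 166 to 4951) and Psat1 (5.5 ± 1.27) rose and the chaperone gene Hyou1 (−1.70 ± 0.45) fell. NRF2 targets rose in 1 of 15 members (1 over the list alone, 3 in the reduced fit), Abcc4 (4.99 ± 1.11). Female-biased genes rose in 2 of 5 members (2 over the list alone, 3 in the reduced fit), among them Fmo2 (5.09 ± 1.24). Fatty acid oxidation genes rose in 1 of 21 members (0 over the list alone, 1 in the reduced fit), Vnn1 (3.23 ± 0.95). With 1 library left out, the test was no longer passed by Jag1 (TdTomato 2 or 3, adjusted p = 0.055 and 0.053) and Nrarp (TdTomato 3 or 4, adjusted p = 0.069 and 0.080). This also held for Eda2r (TdTomato 3 or 4, adjusted p = 0.064 and 0.070) and Slc16a3 (TdTomato 2, 3 or 4, adjusted p = 0.058, 0.060 and 0.067). The call also ended for Hyou1 (TdTomato 2, 3 or 4 or LATS_KO 1 or 2, adjusted p = 0.054 to 0.085) and Psat1 (TdTomato 4, adjusted p = 0.053). Single libraries likewise decided Fmo2 (TdTomato 2 or 4, adjusted p = 0.057 and 0.062) and Vnn1 (TdTomato 2, 3 or 4, LATS_KO 1, 2 or 3 or YAP_OE 1 to 5, adjusted p = 0.052 to 0.11). Leaving out single libraries gave log2 values of 5.14 for Nrarp, 5.20 for Eda2r and 6.29 for Psat1 without TdTomato 2, and 5.81 for Fmo2 without TdTomato 3. Log2 fold changes with 1 library left out were 3.58 for Eda2r without LATS_KO 1, and 3.52 for Pkm without LATS_KO 2. With 1 left out, the log2 values were 6.35 for Phlda3, 2.99 for Nrarp and 4.01 for Abcc4 without LATS_KO 3.

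Cholesterol synthesis genes fell in 10 of 20 members (13 over the list alone, 8 in the reduced fit), with Hmgcs1 (−1.66 ± 0.31), Idi1 (−1.87 ± 0.37) and Fdft1 (−1.32 ± 0.30). Camera placed this list lower than other genes (adjusted p = 2.3e-11), a call lost with an estimated correlation (adjusted p = 0.31). Among urea cycle and amino acid catabolism genes 1 of 20 members (0 over the list alone, 1 in the reduced fit) fell, the tyrosine aminotransferase Tat (−1.42 ± 0.40). Among male-biased genes 1 of 12 members (1 over the list alone, 0 in the reduced fit) fell, Mup20 (−1.89 ± 0.48), and among fatty acid synthesis genes 1 of 17 members (2 over the list alone, 1 and 1 higher in the reduced fit), Acly (−1.20 ± 0.33). No member passed the edgeR test among 20 general hepatocyte genes, 13 periportal, 18 pericentral, 20 cytochrome P450, 20 bile acid, 20 acute phase, 13 gluconeogenesis and 10 immediate early genes, nor when adjusted over each list alone. In this order, 3, 2, 1, 0, 5, 1, 1 and 2 members had an unadjusted p under 0.05, DESeq2 called 1, 0, 1, 0, 4, 1, 0 and 2, and voom 2, 4, 3, 3, 3, 1, 2 and 1. The reduced fit called 1 general hepatocyte gene and 1 bile acid gene lower. Camera placed the first 7 of these lists lower than other genes, from adjusted p = 3.7e-05 for general hepatocyte genes to 0.038 for gluconeogenesis genes, and each call was lost with an estimated correlation (adjusted p = 0.38 for general hepatocyte genes). The LATS_KO libraries were split on some of these lists. The mean log2 CPM of periportal genes was 8.18, 7.26 and 6.33 in LATS_KO 1 to 3, 9.35, 9.34 and 9.48 in LATS_KO 4 to 6, 9.39 to 9.64 in TdTomato and 6.56 to 7.33 in YAP_OE. For cytochrome P450 genes it was 5.76, 4.47 and 5.06 in LATS_KO 1 to 3, 8.15, 8.39 and 8.31 in LATS_KO 4 to 6, 6.84 to 8.45 in TdTomato and 4.70 to 6.39 in YAP_OE. Alb was at 91524 ± 42551 CPM against 103034 ± 30973 CPM (adjusted p = 0.85), and neither Hnf4a (−0.51 ± 0.32, adjusted p = 0.35) nor Cyp7a1 (−1.15 ± 1.03, adjusted p = 0.55) passed the test. Without both TdTomato 1 and LATS_KO 3, Mup20 (−1.30, adjusted p = 0.072) did not pass it. Leaving out 1 library ended the call for Tat (TdTomato 2, 3 or 4 or LATS_KO 1 or 2, adjusted p = 0.067 to 0.085) and Mup20 (TdTomato 1 or 4, adjusted p = 0.072 and 0.060). Also dependent on 1 library was the call for Acly (TdTomato 2 or 3 or LATS_KO 1 or 2, adjusted p = 0.11, 0.096, 0.065 and 0.068).

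The largest rises in this comparison by the fixed rule, ranked by the edgeR log2 fold change, were those of Gpc3 (given above), Ctgf (12.53 ± 1.85), Emp1 (at least 1943-fold higher), Bex1 (at least 361-fold higher) and Glipr2 (at least 357-fold higher). Emp1, Bex1 and Glipr2 were ranked by log2 values fitted over 0 control counts (13.78, 11.62 and 11.49). The lower bounds of Bex1 and Glipr2 are below the ratios of Ankrd1 and Myof given above. Without LATS_KO 2, the lower bounds were 945 (Emp1) and 225 (Bex1). The largest falls were those of Cebpe (−7.93 ± 0.87), Lrit1 (−5.83 ± 0.75), Rnaset2b (−5.63 ± 0.67), Mmd2 (−3.44 ± 0.73) and Lag3 (−3.10 ± 0.80). Cebpe encodes a myeloid transcription factor, and was at 0.0297 ± 0.0372 CPM (SD, n = 6) against 9.59 ± 2.31 CPM (n = 4). Single libraries decided the call for Lag3 (TdTomato 1, adjusted p = 0.083). Values without 1 library were −1.97 for Lag3 without TdTomato 1, and 13.39 for Ctgf without TdTomato 3.

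**Figure D2:**
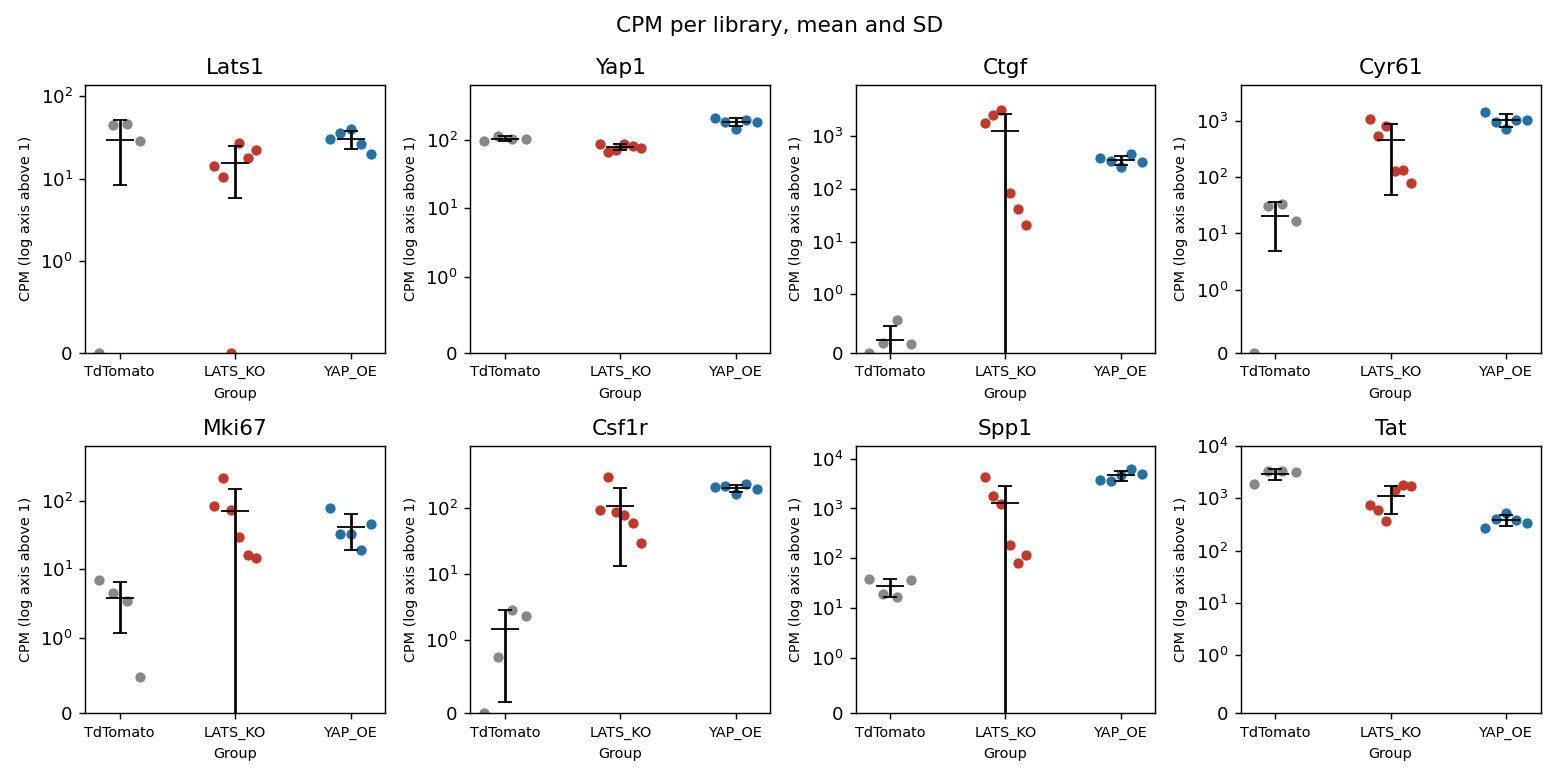
CPM of 8 genes in each library by group, on an axis that is linear up to 1 and logarithmic above. Points are libraries, and bars are the mean and SD, with the SD not drawn below 0. Ctgf spanned 20.6 to 3136 CPM among the LATS_KO libraries and 265 to 465 CPM among the YAP_OE libraries.

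The second comparison asked how livers labelled YAP_OE differed from controls. Most YAP targets, mitotic genes, bile duct markers, matrix genes and macrophage genes were higher, and most genes of amino acid catabolism and periportal metabolism were lower. Cyr61 was at 1021 ± 261 CPM (SD, n = 5) against 20.2 ± 15.3 CPM (n = 4) and Ctgf at 355 ± 74.5 against 0.216 ± 0.238 CPM. The secreted phosphoprotein gene Spp1 was at 4606 ± 1013 against 27.8 ± 11.0 CPM, and Csf1r at 202 ± 24.5 against 1.49 ± 1.33 CPM. Tat was at 386 ± 91.7 against 2995 ± 729 CPM, and Pck1, which encodes a gluconeogenic enzyme, at 454 ± 203 against 5615 ± 1956 CPM.

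Of 13055 genes, 3744 passed the test in edgeR, 2332 higher and 1412 lower, or 62.3% higher. With RLE factors 70.4% of the called genes were higher, and the median of all genes moved by 0.18 on the log2 scale, so falls of about this size are not shown. Without TdTomato 1 and LATS_KO 3, 6416 genes were called, of which 3613 were shared in the same direction. Of the 119 named genes past the test, 115 passed it without each of the 15 libraries in turn.

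YAP/TEAD targets rose in 17 of 20 members (17 over the list alone, 18 and 1 lower in the reduced fit), with the smallest p for Ankrd1 (ratio 13880, 95% interval 2491 to 548249), Axl (6.67 ± 1.02) and Myof (ratio 1993, 95% interval 551 to 16458). Cyr61 rose by 5.66 ± 1.20 and Ctgf by 10.70 ± 1.76. All 24 G2/M and mitosis genes rose (24 over the list alone, 24 in the reduced fit), with Kif23 (6.22 ± 1.04), Nusap1 (5.02 ± 0.95), Ccnb2 (4.49 ± 0.89) and Mki67 (3.46 ± 0.86). DNA replication genes rose in 19 of 24 members with 1 lower (19 and 1 lower over the list alone, 22 and 1 lower in the reduced fit), such as Uhrf1 (6.36 ± 1.19), Cdc6 (ratio 111, 95% interval 37.9 to 541) and Mcm5 (4.41 ± 0.90). Hippo components rose in 9 of 22 members with 1 lower (9 and 1 lower over the list alone, 12 and 2 lower in the reduced fit), including Tead2 (7.21 ± 1.31) and Tead4 (at least 501-fold higher). Among p53 targets 12 of 18 members (12 and 1 lower over the list alone, 11 and 1 lower in the reduced fit) rose, including Phlda3 (9.29 ± 1.29), Ccng1 (1.59 ± 0.25) and Eda2r (7.12 ± 1.25). Notch pathway genes rose in 7 of 12 members with 1 lower (8 and 1 lower over the list alone, 8 and 1 lower in the reduced fit), with Jag2 (at least 17.7-fold higher) and Hes1 (2.35 ± 0.39) higher and Hes6 (−2.58 ± 0.56) lower. Leaving out single libraries gave log2 values of 7.31 for Uhrf1 and 7.97 for Eda2r without TdTomato 2, and 11.56 for Ctgf, 5.74 for Nusap1, 5.14 for Ccnb2 and 8.23 for Tead2 without TdTomato 3. Axl had a log2 fold change of 7.39 without TdTomato 4.

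Cholangiocyte markers rose in 12 of 14 members (12 over the list alone, 12 in the reduced fit), including Prom1 (9.20 ± 1.45), Epcam (6.84 ± 1.10), Spp1 (7.37 ± 1.19), Krt19 (5.59 ± 1.43) and Sox9 (3.02 ± 0.73). Matrix genes rose in 21 of 26 members (22 over the list alone, 23 in the reduced fit), such as Sparc (6.03 ± 0.77), Col3a1 (9.02 ± 1.34) and Timp2 (9.83 ± 1.5). Col1a1 was at least 254-fold higher than a control level of 0 counts. Stellate cell and fibroblast markers rose in 13 of 16 members (14 over the list alone, 14 in the reduced fit), with Lum (ratio 199, 95% interval 35.4 to 7861), Acta2 (at least 39.6-fold higher) and Col14a1 (5.12 ± 1.31). The lower bound was 23.7 (Acta2) without YAP_OE 4. Fetal liver and tumour-associated genes rose in 8 of 13 members with 1 lower (8 and 1 lower over the list alone, 8 and 2 lower in the reduced fit), with H19 (ratio 869, 95% interval 156 to 34344), Gpc3 (ratio 67891, 95% interval 12185 to 2681570), Cd24a (ratio 236, 95% interval 80.5 to 1144) and Afp (5.02 ± 1.27). Sinusoidal endothelial markers rose in 6 of 18 members (6 over the list alone, 12 in the reduced fit), with Flt4 (1.90 ± 0.49), Maf (0.80 ± 0.22) and Rspo3 (ratio 18.7, 95% interval 5.01 to 157). Log2 fold changes with 1 library left out were 10.56 for Timp2 and 5.88 for Col14a1 without TdTomato 2, and 10.85 for Col3a1 without TdTomato 3. Krt19 had a log2 fold change of 6.63 without TdTomato 4.

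Part of the immune markers rose here too, with the same limit from the few transcripts of such cells in the controls. Inflammatory monocyte markers were higher in 8 of 10 members (8 over the list alone, 8 in the reduced fit), with Csf1r (7.06 ± 0.92), Fcgr1 (5.77 ± 1.07) and Ms4a6c (ratio 76.8, 95% interval 26.1 to 374). Ccr2 had a ratio of 85.7 (95% interval 29.2 to 417) from 3 control counts. Ly6c2 was not tested, at 0.138 ± 0.107 CPM (SD, n = 5). Macrophage markers rose in 13 of 15 members (14 over the list alone, 12 in the reduced fit), with Ctss (6.13 ± 0.95), Lyz2 (5.72 ± 0.93), Lgals3 (ratio 239.97, 95% interval 82.0 to 1165) and Adgre1 (5.58 ± 1.27). Kupffer cell markers rose in 7 of 12 members (12 over the list alone, 11 in the reduced fit), with Clec4f (4.19 ± 0.89), Vsig4 (5.60 ± 1.26) and Timd4 (5.42 ± 1.36). Neutrophil markers rose in 1 of 5 members (2 over the list alone, 2 in the reduced fit), Csf3r (3.28 ± 1.05). With 1 library left out, the test was no longer passed by Csf3r (TdTomato 2 or 4 or YAP_OE 3 or 4, adjusted p = 0.081, 0.064, 0.055 and 0.055). With 1 left out, the log2 values were 6.58 for Fcgr1, 7.25 for Ctss, 6.60 for Lyz2, 6.30 for Adgre1 and 6.32 for Vsig4 without TdTomato 4.

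Chemokines and growth factors that recruit monocytes rose in 8 of 9 members (8 over the list alone, 8 in the reduced fit), including Ccl2 (ratio 414, 95% interval 115 to 3425), Csf1 (5.92 ± 1.21) and Cxcl16 (2.52 ± 0.55). CXC chemokines rose in 3 of 8 members with 1 lower (3 and 1 lower over the list alone, 3 and 2 lower in the reduced fit), with Cxcl13 (4.95 ± 1.08) and Cxcl10 (2.84 ± 0.81) higher and Cxcl12 (−1.07 ± 0.26) lower. Inflammatory cytokines and receptors rose in 7 of 12 members (8 and 1 lower over the list alone, 8 and 2 lower in the reduced fit), with Il1b (5.97 ± 1.19), Tnfrsf12a (4.03 ± 0.86) and Lif (ratio 678, 95% interval 121 to 26793). MHC class II and interferon-gamma genes rose in 9 of 16 members (9 and 1 lower over the list alone, 9 in the reduced fit), with H2-Eb1 (5.40 ± 0.94), Cd74 (4.86 ± 0.88) and H2-DMb1 (ratio 67.9, 95% interval 23.1 to 330.4). Type I interferon genes rose in 4 of 23 members (4 over the list alone, 10 and 1 lower in the reduced fit), with Ifit2 (5.43 ± 0.93), Oas2 (ratio 65.3, 95% interval 17.9 to 542) and Oas3 (ratio 45.5, 95% interval 12.4 to 378). Immediate early genes, a list fixed as one of tissue handling, rose in 5 of 10 members (8 over the list alone, 5 in the reduced fit), with Dusp1 (1.41 ± 0.33), Fos (2.77 ± 0.65) and Egr2 (4.89 ± 1.19). The mean log2 CPM of this list was 2.40 to 5.93 in TdTomato and 6.82 to 7.54 in YAP_OE. Unlike handling of the samples cannot be told apart from the group here. NRF2 targets rose in 6 of 15 members with 1 lower (6 and 1 lower over the list alone, 6 and 1 lower in the reduced fit), with Osgin1 (2.28 ± 0.30) and Abcc4 (5.53 ± 1.15) higher and Me1 (−1.43 ± 0.33) lower. ER stress and ATF4 targets moved both ways, 3 of 17 members higher and 8 lower (3 and 9 over the list alone, 3 and 9 in the reduced fit), with Phgdh (ratio 1647, 95% interval 456 to 13604) and Psat1 (6.46 ± 1.33) higher and Creld2 (−2.54 ± 0.55) lower. Glycolysis genes did so too, 4 of 13 members higher and 4 lower (5 and 4 over the list alone, 6 and 4 in the reduced fit), with Hk2 (ratio 54.0, 95% interval 18.3 to 263) and Pkm (3.17 ± 0.78) higher and Pgk1 (−1.11 ± 0.23) lower. Values without 1 library were 5.75 for Cxcl13, 6.13 for Ifit2 and 7.25 for Psat1 without TdTomato 2, and 5.59 for Egr2 without TdTomato 3.

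All 20 urea cycle and amino acid catabolism genes fell (20 over the list alone, 20 in the reduced fit), including Got1 (−2.54 ± 0.32), Tat (−2.95 ± 0.43) and Arg1 (−2.49 ± 0.44). Periportal genes fell in 12 of 13 members (13 over the list alone, 13 in the reduced fit), with Pck1 (−3.63 ± 0.62) and Cyp2f2 (−4.21 ± 0.86). Pericentral genes fell in 1 of 18 members (0 over the list alone, 2 and 1 higher in the reduced fit). Camera placed the catabolism and periportal lists lower than other genes (adjusted p = 5.0e-13 and 1.3e-08), and both calls were lost with an estimated correlation (adjusted p = 0.31 and 0.31). Cytochrome P450 genes fell in 10 of 20 members (13 over the list alone, 15 in the reduced fit), such as Cyp2f2 (−4.21 ± 0.86), Cyp2d26 (−2.80 ± 0.59) and Cyp2d9 (−2.21 ± 0.47). Male-biased genes fell in 10 of 12 members (11 over the list alone, 11 in the reduced fit), with Mup20 (−3.72 ± 0.54) and Cyp7b1 (−4.71 ± 0.96). Bile acid genes fell in 12 of 20 members with 1 higher (12 and 1 higher over the list alone, 14 and 1 higher in the reduced fit), with Nr0b2 (−3.18 ± 0.78) lower and Fgfr4 (0.90 ± 0.22) higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass the test (0.54 ± 1.10, adjusted p = 0.76). Female-biased genes gave 1 of 5 members higher and 1 lower (1 and 1 over the list alone, 2 and 1 in the reduced fit), Fmo2 (5.53 ± 1.28) higher and Cyp17a1 (−4.42 ± 1.28) lower. Leaving out 1 library ended the call for Cyp17a1 (TdTomato 4 or YAP_OE 4, adjusted p = 0.080 and 0.0501). Leaving out single libraries gave log2 values of 6.26 for Fmo2 without TdTomato 3, and −3.21 for Cyp17a1 without TdTomato 4.

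Other metabolic lists fell in part. Gluconeogenesis and glycogen genes fell in 6 of 13 members (7 over the list alone, 8 in the reduced fit), with Pck1 and Pygl (−1.72 ± 0.42) and Slc37a4 (−1.19 ± 0.30). Fatty acid synthesis genes fell in 6 of 17 members (7 over the list alone, 11 and 1 higher in the reduced fit), with Elovl6 (−1.31 ± 0.33), Acacb (−3.28 ± 0.86) and Acly (−1.25 ± 0.35). Cholesterol synthesis genes fell in 9 of 20 members (14 over the list alone, 15 in the reduced fit), with Msmo1 (−1.99 ± 0.50), Fdps (−1.95 ± 0.50) and Idi1 (−1.47 ± 0.39). Acute phase genes fell in 6 of 20 members (9 over the list alone, 13 in the reduced fit), with Orm1 (−3.03 ± 0.66), Saa3 (−3.67 ± 0.92) and Lrg1 (−1.95 ± 0.52). Fatty acid oxidation genes fell in 6 of 21 members with 3 higher (12 and 3 higher over the list alone, 14 and 3 higher in the reduced fit), including Acadvl (−1.48 ± 0.31), Cpt2 (−1.71 ± 0.37) and Ehhadh (−2.02 ± 0.58). Among general hepatocyte genes 5 of 20 members (9 over the list alone, 13 in the reduced fit) fell, including Mat1a (−1.44 ± 0.25), Apoc3 (−2.73 ± 0.60) and F9 (−1.77 ± 0.41). Alb was at 91598 ± 22926 CPM against 103034 ± 30973 CPM (adjusted p = 0.81) and Hnf4a did not pass the test (−0.86 ± 0.34, adjusted p = 0.066). Hnf4a passed it as lower without TdTomato 1 (−1.13, adjusted p = 0.010), without LATS_KO 3 (−0.86, adjusted p = 0.046) and in the reduced fit (−1.13, adjusted p = 0.0029). Single libraries decided the call for Lrg1 (TdTomato 4, adjusted p = 0.061) and Acly (TdTomato 2, adjusted p = 0.052). Log2 fold changes with 1 library left out were −2.78 for Saa3 without TdTomato 4, and −4.15 for Acacb without YAP_OE 3. Saa3 had a log2 fold change of −4.37 without YAP_OE 5.

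By the fixed rule, ranked by the edgeR log2 fold change, the largest rises were those of Gpc3 (given above), Fgfbp1 (at least 4702-fold higher), Psca (at least 2393-fold higher), Emp1 (at least 2400.3-fold higher) and Scn7a (at least 1807-fold higher). All but Gpc3 were ranked by log2 values fitted over 0 control counts (15.17, 14.20, 14.17 and 13.80, in this order). Their lower bounds are below the ratio of Ankrd1 given above. The largest falls were those of Serpina3c (−6.57 ± 1.47), Ugt2b38 (−6.30 ± 1.35), Elovl3 (−6.01 ± 1.46), Mup7 (−5.91 ± 1.51) and Mup8 (−5.81 ± 1.55), members of near-identical families apart from Elovl3, which encodes a fatty acid elongase. In the reduced fit these falls were −4.48, −5.96, −5.95, −5.71 and −5.02, in this order, so the first was then the smallest. TdTomato 1 had 124 CPM of Serpina3c, against at most 19.5 CPM in the other controls. With 1 left out, the log2 values were −4.46 for Serpina3c and −5.00 for Mup8 without TdTomato 1, and −6.89 for Ugt2b38, −6.95 for Elovl3 and −6.99 for Mup7 without YAP_OE 5.

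**Figure D3:**
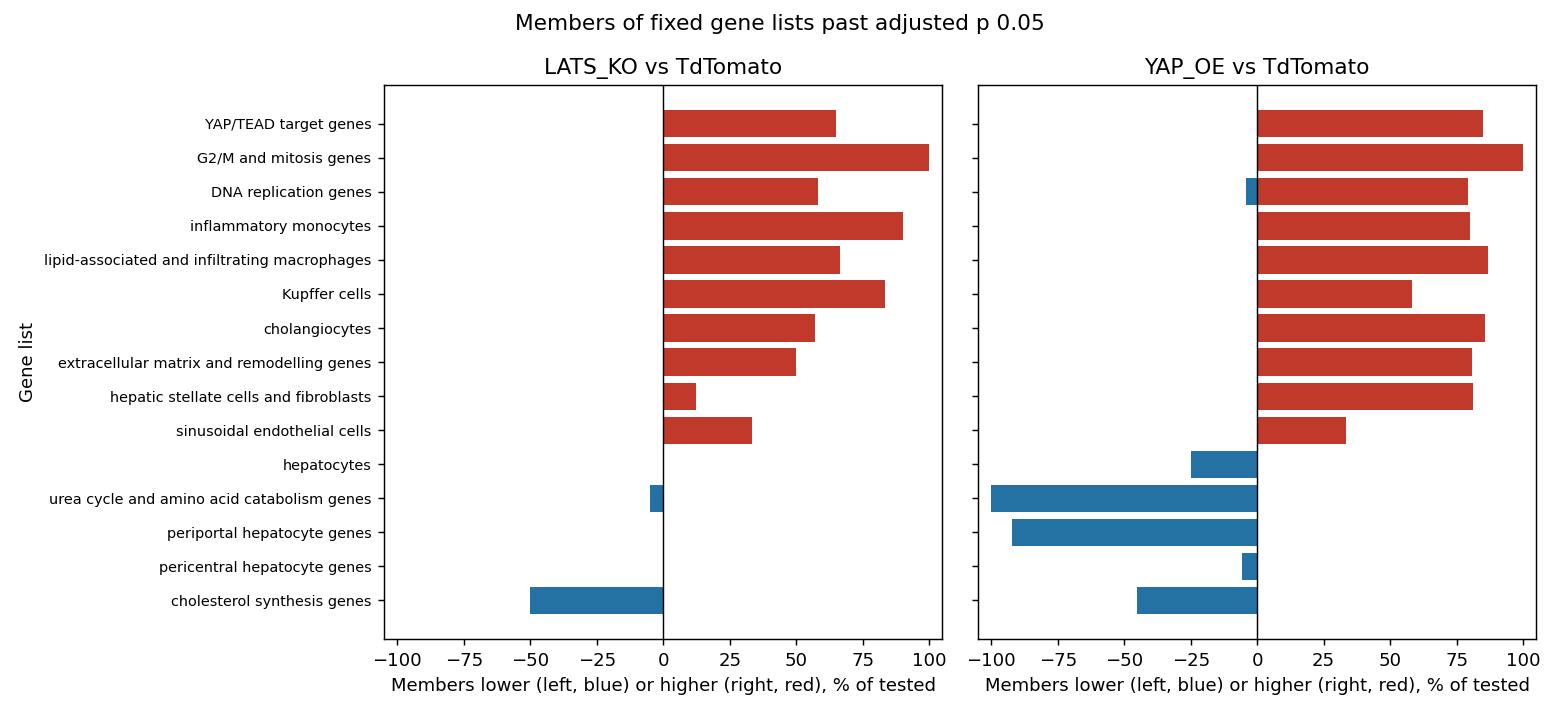
Share of tested members of 15 fixed gene lists that passed the test as higher (red, to the right) or lower (blue, to the left) in LATS_KO and in YAP_OE, each against TdTomato. All 24 G2/M and mitosis genes rose in both comparisons, and all 20 urea cycle and amino acid catabolism genes fell in YAP_OE, against 1 in LATS_KO, where the libraries were split. The mean log2 CPM of these genes was 7.79, 6.96 and 6.65 in LATS_KO 1 to 3, 9.44, 9.50 and 9.50 in LATS_KO 4 to 6, 9.39 to 9.76 in TdTomato and 6.55 to 7.47 in YAP_OE.

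The third comparison set YAP_OE against LATS_KO directly. Yap1 was higher in YAP_OE by 1.23 ± 0.15 (adjusted p = 0.0012). The fetal liver genes H19 (7.92 ± 0.88) and Mdk (3.84 ± 0.86), the collagens Col3a1 (5.16 ± 0.88) and Col1a2 (4.15 ± 0.86), and the bile duct gene Epcam (4.48 ± 0.80) were higher. So were the YAP target Arhgef17 (4.82 ± 1.05), the p53 target Ccng1 (1.03 ± 0.21) and the NRF2 target Osgin1 (1.64 ± 0.26). The amino acid enzyme Got1 (−2.07 ± 0.30), the glucose-producing Slc37a4 (−1.39 ± 0.28) and Pck1 (−2.80 ± 0.57) and the periportal Hsd17b13 (−1.18 ± 0.25) were lower. With 1 library left out, the test was no longer passed by Mdk (TdTomato 2, 3 or 4, LATS_KO 1, 4 or 5 or YAP_OE 1 to 5, adjusted p = 0.063 to 0.15) and Col3a1 (YAP_OE 4, adjusted p = 0.056). This also held for Col1a2 (LATS_KO 1, 4, 5 or 6 or YAP_OE 1, 2, 3 or 4, adjusted p = 0.056 to 0.14) and Epcam (YAP_OE 4, adjusted p = 0.056). The call also ended for Arhgef17 (TdTomato 2, 3 or 4, LATS_KO 1, 4, 5 or 6 or YAP_OE 1 to 5, adjusted p = 0.054 to 0.14) and Ccng1 (LATS_KO 4, 5 or 6 or YAP_OE 1, 2, 3 or 4, adjusted p = 0.065 to 0.14). Single libraries likewise decided Slc37a4 (LATS_KO 4, 5 or 6 or YAP_OE 1, 2, 3 or 4, adjusted p = 0.056 to 0.12) and Pck1 (LATS_KO 4, 5 or 6 or YAP_OE 1 to 5, adjusted p = 0.057 to 0.12). Also dependent on 1 library was the call for Hsd17b13 (TdTomato 2, 3 or 4, LATS_KO 1, 4, 5 or 6 or YAP_OE 1 to 5, adjusted p = 0.052 to 0.15). Arhgef17 had a log2 fold change of 6.25 without LATS_KO 2.

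The test was passed by 129 of 13055 genes in edgeR, 65 higher and 64 lower. Without TdTomato 1, LATS_KO 2 and LATS_KO 3 in turn there were 368, 312 and 389, and without LATS_KO 4, LATS_KO 5, LATS_KO 6, YAP_OE 1, YAP_OE 2, YAP_OE 3, YAP_OE 4 and YAP_OE 5 in turn 60, 61, 71, 46, 45, 59, 36 and 72. Without both TdTomato 1 and LATS_KO 3 there were 1688, which included all 129 in the same direction. The largest rises were those of Hao2 (ratio 466, 95% interval 129 to 3856), H19 (given above), Adamdec1 (6.93 ± 1.00), Myo5c (6.28 ± 1.06) and Vldlr (6.13 ± 0.68). The largest falls were those of Tmc5 (−6.71 ± 1.29), Jchain (−5.93 ± 0.94), Tiam2 (−4.13 ± 0.50), Etnppl (−2.80 ± 0.44) and Eif4ebp3 (−2.18 ± 0.29). Leaving out 1 library ended the call for Tmc5 (YAP_OE 1, 2, 4 or 5, adjusted p = 0.087, 0.073, 0.10 and 0.069). Values without 1 library were 7.03 for Myo5c without LATS_KO 2, and 7.92 for Adamdec1 without LATS_KO 6. Tmc5 had a log2 fold change of −7.67 without YAP_OE 3.

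Of the lists, Hippo components had 1 of 22 members (1 over the list alone, 3 in the reduced fit) higher, YAP/TEAD targets 1 of 20 members (1 over the list alone, 3 in the reduced fit), matrix genes 2 of 26 members (11 over the list alone, 8 in the reduced fit), fetal liver genes 2 of 13 members (3 over the list alone, 3 in the reduced fit), p53 targets 1 of 18 members (7 and 1 lower over the list alone, 6 and 1 lower in the reduced fit), cholangiocyte markers 1 of 14 members (5 and 1 lower over the list alone, 3 in the reduced fit) and NRF2 targets 1 of 15 members (1 over the list alone, 1 in the reduced fit). Lower members were 1 of 20 members (17 over the list alone, 17 in the reduced fit) among catabolism genes, 2 of 13 members (5 over the list alone, 7 in the reduced fit) among gluconeogenesis genes and 2 of 13 members (10 over the list alone, 10 in the reduced fit) among periportal genes. With all libraries, members of further lists passed only when adjusted over the list alone, with 7 stellate cell markers higher and 1 lower, 2 Notch genes and 2 immediate early genes higher. There, 6 bile acid, 8 cytochrome P450, 8 male-biased and 2 female-biased genes were lower, and fatty acid oxidation genes went both ways, 1 higher and 2 lower. The same held for 1 glycolysis, 1 macrophage and 1 general hepatocyte gene, each lower. No member of the monocyte, Kupffer cell, mitosis or DNA replication lists passed the test in edgeR, where 1, 1, 0 and 1 had an unadjusted p under 0.05, DESeq2 called 1, 0, 0 and 0, and voom 4, 7, 1 and 18. The edgeR test also called none in the monocyte-recruiting, CXC, cytokine, interferon, MHC, neutrophil, endothelial, acute phase, ER stress, cholesterol, fatty acid synthesis and pericentral lists. In this order 1, 1, 1, 2, 1, 1, 0, 5, 3, 1, 2 and 1 had an unadjusted p under 0.05, DESeq2 called 0, 0, 1, 2, 1, 0, 0, 1, 0, 0, 1 and 0, and voom 7, 3, 6, 7, 5, 1, 8, 13, 15, 5, 14 and 6. The reduced fit called 0, 0, 0, 3, 1, 0, 0, 0, 0, 0, 0 and 1 higher and 0, 1, 2, 0, 0, 1, 1, 6, 1, 0, 1 and 0 lower.

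Genes chosen for the study's subject did not pass the test of edgeR between YAP_OE and LATS_KO, which does not show that they were equal. The YAP targets tested were Ctgf (−1.83 ± 1.01, adjusted p = 0.44), Cyr61 (1.17 ± 0.85, adjusted p = 0.61) and Ankrd1 (2.52 ± 0.95, adjusted p = 0.22). The proliferation and immune genes were Mki67 (−0.79 ± 0.69, adjusted p = 0.71), Ccr2 (−0.40 ± 0.96, adjusted p = 0.94), Ccl2 (−1.21 ± 0.95, adjusted p = 0.65), Adgre1 (0.18 ± 0.88, adjusted p = 0.98) and Clec4f (0.15 ± 0.67, adjusted p = 0.97). Bile duct, matrix and fetal genes were Krt19 (0.11 ± 0.97, adjusted p = 0.98), Sox9 (0.67 ± 0.59, adjusted p = 0.71), Spp1 (1.86 ± 0.79, adjusted p = 0.28), Col1a1 (2.90 ± 1.04, adjusted p = 0.21) and Afp (0.89 ± 0.92, adjusted p = 0.77). Hepatocyte genes were Alb (0.0012 ± 0.39, adjusted p = 1.00), Hnf4a (−0.35 ± 0.31, adjusted p = 0.71) and Cyp7a1 (1.69 ± 0.99, adjusted p = 0.48). Lats1 (0.99 ± 0.95, adjusted p = 0.75), Lats2 (1.41 ± 0.70, adjusted p = 0.37) and Wwtr1 (0.32 ± 0.45, adjusted p = 0.87) did not pass it either. With voom, Ctgf (2.40, adjusted p = 0.0015) and Ccl2 (2.10, adjusted p = 0.0057) were higher in YAP_OE and Alb (−0.51, adjusted p = 0.029) lower, past the threshold and opposite in sign to edgeR. Voom also called Lats2, Wwtr1, Cyr61, Ankrd1, Krt19, Sox9, Spp1, Col1a1 and Afp higher and Hnf4a lower, in the same direction as edgeR. Lats2 passed the edgeR test without TdTomato 1 (1.41, adjusted p = 0.031), and in the reduced fit so did Lats2 (1.24, adjusted p = 0.012) and Ankrd1 (3.53, adjusted p = 0.036).

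Across the 37 lists tested, camera called 16 lists higher and 13 lower in LATS_KO, 19 and 12 in YAP_OE, and 9 and 10 in YAP_OE against LATS_KO. With an estimated correlation 0 of these 79 calls held, and fry made 54 calls over the 3 comparisons, 5 of them not made by camera. Signs differed within some lists. For ER stress genes camera and the median (−0.46 in LATS_KO and −0.73 in YAP_OE) were below 0 and the mean above it, at 0.54 and 0.33. Fatty acid oxidation genes in LATS_KO had a median of −0.41 and a mean of 0.12. Camera placed type I interferon genes lower in LATS_KO (adjusted p = 0.91), with a median of 0.40 and a mean of 1.01, and glycolysis genes lower in YAP_OE (adjusted p = 0.99), with a median of 0.31 and a mean of 1.27. In YAP_OE against LATS_KO, camera was above 0 and the median and mean below it for pericentral, macrophage, Kupffer cell and endothelial lists, none of which was called.

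The log2 fold changes of LATS_KO and YAP_OE against TdTomato had a Pearson r of 0.92 and a Spearman rho of 0.87 across 13055 genes, which are not independent replicates. The controls are shared, and simulated groups with no effect gave an r of 0.61. With the controls split in the 6 possible ways the mean r was 0.80. The covariance was 4.01, against 0.35 in the simulation, and 4.02 with the controls split. A split removes only the noise of single control libraries, so what all controls had in common stays in both sets of fold changes. The correlation therefore cannot tell a shared response from a shared trait of the controls. Of the genes called higher, 1216 were called in both comparisons, against 234 for independent lists and 0 in the simulation. Of those called lower, 103 were, against 13.7 and 0. Neither figure can show how much of the overlap the shared controls give. The simulation held no effect, so hardly any gene could be called in it, and the figure for independent lists ignores the shared controls. With the controls split, which leaves 2 per comparison, a mean of 20.8 were called higher and 1 lower in both.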

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

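The tests of explanations in this part were chosen after the results were seen. Of 74 sets of values within groups that were examined for a single library far from the rest, 13 had one, where 3.7 would be expected by chance. Most concerned TdTomato 1 and LATS_KO 3, or LATS_KO 1 and 2.

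TdTomato 1 and LATS_KO 3 stood apart in unmapped reads, 78.5% and 89.9% against at most 13.3% and 16.7% in the rest of their groups, and in genes detected, 8501 and 9710 against at least 13372 and 14085. Lower depth is argued against: at equal depth the higher of the 2 still detected only 78.6% of the genes found in the lowest of the other 13 libraries. Few distinct molecules may have entered these libraries, since 9.26% (LATS_KO 3) and 16.5% (TdTomato 1) of 6752 genes at 10 to 100 CPM elsewhere had 0 counts, against at most 0.529% in the others. TdTomato 1 also had the lowest control values of Lats2 (0 CPM, next 17.4) and Cyp7a1 (30.4 CPM, next 35.3). No biological explanation was tested, because the labels give none for these 2 libraries.

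Among the 6 LATS_KO libraries, LATS_KO 2 was highest for Mki67 (216 CPM, next 84.9), Ccr2 (21.8, next 4.38), Krt19 (18.5, next 3.44) and Col1a1 (6.14, next 1.45), and LATS_KO 1 for Sox9 (159, next 62.9). The single highest controls for Ankrd1 (TdTomato 2, 0.0552 CPM) and Ccl2 (TdTomato 4, 0.0958 CPM) rest on 1 and 2 counts, with 0 in the other controls.

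The YAP/TEAD targets also differed among the LATS_KO libraries, with mean log2 CPM of 5.03, 5.73, 4.37, 2.81, 2.20 and 2.10 in LATS_KO 1 to 6. Libraries like the controls here under a LATS_KO label are argued against, because even the lowest library had 12 of 20 targets above every control. Control livers with more transcripts of other cells are not excluded by this count. The mean log2 CPM of Kupffer cell markers was 4.42, 4.16 and 3.32 in LATS_KO 4 to 6, against −1.90 to 0.525 in TdTomato. The share of mapped reads outside genes could still account for part of the difference (r = −0.90, exact p = 0.017, adjusted over 2 relations 0.033, n = 6). However, the libraries form 2 clusters with a gap of 52.8% of the range, and without LATS_KO 1 and 2 r was −0.60. LATS_KO 3 and 4 had similar shares but target scores of 4.37 and 2.81, a step that the share leaves unexplained. This step rests on LATS_KO 3, in which most reads were unmapped. The extent of Lats1 loss, the biological explanation the design gives, also stays open, since whole-gene counts, the only measure here, do not check the deletion. Against Lats1 counts the scores gave no clear relation (r = −0.33, exact p = 0.70), where LATS_KO 3 with 0 counts alone makes 83.2% of the range of Lats1, and without LATS_KO 3 and 4 r was −0.93. With 6 libraries these 2 explanations cannot be told apart.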

How the results depend on the processing

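The fit without TdTomato 1 and LATS_KO 3 was chosen after seeing the data. All other alternatives and the splits of the samples were planned.

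The number of genes called in LATS_KO against TdTomato, 1438, was 2894 with DESeq2, 3501 with voom, 1 with only the 2 groups fitted, 740 with the replicate number as a block, 2325 with a surrogate variable and 2245 without TdTomato 1 and LATS_KO 3. The genes shared with the 1438 in the same direction were 1419, 1186, 1, 621, 1398 and 1245. Leaving out 1 library gave 588 to 1798. With RLE factors there were 1609, without a filter 1308, with a mean count of at least 50 969, and with unstranded counts 1364. Few splits of the libraries gave as many genes, 3 of 100 (drawn from 210) with the real one included. The rule fixed beforehand counted a share under 0.05 as arguing against chance as the grouping, and it was met. Wrong splits still gave more genes than the real one, so chance as the grouping is not excluded for this count. The highest other gave 2281, by setting TdTomato 2, 3 and 4 with LATS_KO 4, 5 and 6 against the rest. This split parts LATS_KO 1, 2 and 3 from LATS_KO 4, 5 and 6 and points to a structure of the samples.

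In YAP_OE against TdTomato, 3744 became 8868 with voom and 6416 without TdTomato 1 and LATS_KO 3, with 3731 and 3613 shared. The other settings gave 2796 (mean count of at least 50) to 5478 (surrogate variable), and leaving out 1 library 2585 to 4973. No other of the 100 splits (drawn from 126) gave as many, the highest other being 0, which argues against chance as the grouping. In YAP_OE against LATS_KO, 129 became 779 with DESeq2, 7325 with voom, 13 with the block (12 shared), 676 with a surrogate variable and 1688 without TdTomato 1 and LATS_KO 3, and leaving out 1 library gave 36 to 389. Here 4 of 100 splits (drawn from 462) gave as many genes, the real one included. The rule of a share under 0.05 was met here too. Wrong splits again gave more genes than the real one, so chance as the grouping is not excluded. The highest other gave 588, by setting LATS_KO 1, 4, 5 and 6 and YAP_OE 5 against the rest, which points to another structure of the samples. The cause of either was not tested.

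The share of called genes that were higher in LATS_KO, 91.2%, was 60.1% with voom and 78.6% with the block, and in YAP_OE against LATS_KO 50.4% became 34.5% with a surrogate variable and 69.2% with the block. Voom moved the median of all genes by −0.15 in LATS_KO and −0.19 in YAP_OE. Replicate numbers did not pair the samples, so the block has no known basis. Of the list calls, 0 held with an estimated correlation, and leaving out 1 library gave 73 to 81 calls. The correlation of the 2 sets of fold changes was 0.89 to 0.92 with 1 library left out.

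Of the named genes past the test, the fit of only 2 groups lost 83 of 89 in LATS_KO, 0 of 119 in YAP_OE and 3 of 22 in YAP_OE against LATS_KO, and the block lost 32, 4 and 15. DESeq2 gave no adjusted p to 2 of those in LATS_KO, Marco (7.15 ± 1.17) and Ccl6 (6.40 ± 1.06), and kept the calls of all others. Voom lost 10, 0 and 0.

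Other settings called named genes that had not passed the test. In LATS_KO these were Lats1 (−1.10, adjusted p = 0.025) without TdTomato 1 and LATS_KO 3, Yap1 (−0.35, adjusted p = 0.016) with DESeq2, and Yap1 (−0.41, adjusted p = 0.013) and Hnf4a (−0.50, adjusted p = 0.040) with voom. In YAP_OE they were Lats2 (1.58, adjusted p = 0.0022) and Hnf4a (−1.13, adjusted p = 0.0029) without TdTomato 1 and LATS_KO 3, Lats2 (1.62, adjusted p = 1.7e-06), Alb (−0.56, adjusted p = 0.013) and Hnf4a (−0.95, adjusted p = 3.5e-05) with voom, and Lats1 (0.82, adjusted p = 0.041), Lats2 (2.13, adjusted p = 0.035) and Hnf4a (−0.85, adjusted p = 0.021) with a surrogate variable. Lats2 was also called there with DESeq2 (2.23, adjusted p = 0.016) and RLE factors (2.23, adjusted p = 0.048). In YAP_OE against LATS_KO voom called Lats2 (1.71, adjusted p = 2.7e-06), Wwtr1 (1.43, adjusted p = 8.0e-06), Cyr61 (2.74, adjusted p = 7.1e-06), Ankrd1 (6.51, adjusted p = 1.6e-07), Krt19 (2.85, adjusted p = 0.0057), Sox9 (2.60, adjusted p = 2.8e-06), Spp1 (4.87, adjusted p = 1.7e-06), Col1a1 (4.09, adjusted p = 3.3e-04), Afp (4.01, adjusted p = 4.2e-04) and Hnf4a (−0.45, adjusted p = 0.019), a surrogate variable Ankrd1 (3.72, adjusted p = 0.036), and the fit without TdTomato 1 and LATS_KO 3 Lats2 (1.24, adjusted p = 0.012) and Ankrd1 (3.53, adjusted p = 0.036).

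The log2 values that changed sign belonged to genes that had not passed the test. In LATS_KO these were Lats1 with a surrogate variable (0.068), Lats2 with voom (−0.096) and Alb with 1 library left out (−0.34 to 0.010). In YAP_OE they were Lats1 with voom (−0.32), without TdTomato 1 and LATS_KO 3 (−0.37) and with 1 left out (−0.37 to 0.33), and Cyp7a1 with a surrogate variable (−0.16) and with 1 left out (−0.12 to 0.79). In YAP_OE against LATS_KO voom reversed Ctgf (2.40, adjusted p = 0.0015), Ccl2 (2.10, adjusted p = 0.0057), Alb (−0.51, adjusted p = 0.029), Mki67 (0.42), Ccr2 (0.67), Adgre1 (−0.31) and Clec4f (−0.71). The block reversed Ccr2 (0.25), and a surrogate variable Adgre1 (−0.14) and Alb (−0.16). Without TdTomato 1 and LATS_KO 3, Adgre1 (−0.088), Clec4f (−0.086) and Alb (−0.18) changed sign. With 1 library left out the ranges were −0.66 to 0.98 (Ccr2), −0.085 to 0.56 (Adgre1), −0.16 to 0.47 (Clec4f), −0.14 to 1.42 (Krt19) and −0.18 to 0.15 (Alb).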

Other observations

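The tests in this part were chosen after the results were seen. Transcripts of macrophages, bile duct cells and matrix-producing cells were higher in YAP_OE than in TdTomato. Those of periportal metabolism were lower, and Alb did not pass the test. A smaller share of hepatocytes in the tissue might produce both changes at once. With the mix of the other cells unchanged, it should raise the markers of every other cell type alike. An unequal rise of other cells also lowers the share of hepatocytes, so unequal medians argue only against that even form. The medians of the marker lists were 4.14 (Kupffer cells), 4.80 (macrophages), 4.12 (stellate cells), 4.46 (cholangiocytes) and 1.90 (endothelial cells) on the log2 scale. Members with 0 control counts, 4 macrophage and 1 stellate cell markers, enter at their lower bound, and the macrophage median from edgeR values alone was 5.58. The medians spanned a range of 2.90 (permutation p = 0.023). Among members under 5 CPM in controls, 11 of 12, 13 of 15, 16 of 16, 9 of 14 and 10 of 18, the range was 3.61 (permutation p = 3.2e-04). That limit selects on control values that also enter the folds. The permutations shuffled genes between lists, and genes of a list are not independent. Their p-values therefore do not measure the spread between libraries.

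The losses within hepatocyte genes also argue against an even loss of hepatocytes as the only cause. Periportal genes had a median log2 fold change of −2.49 and pericentral genes of −0.90, a difference of −1.59 (permutation p = 3.5e-04), where a common dilution would lower both alike. Genes were shuffled for this p-value too, so it has the same limit. A change in single cell types, such as more macrophages, or in expression within cells stays open, since no cells were counted here. The controls held few transcripts of other cells, with Col1a1 at 0 CPM in TdTomato 1 to 4 and Adgre1 at most at 0.718 CPM. What the control tissue held therefore also enters these folds, and it cannot be told apart from the group.

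Another hypothesis concerns the genes lower in LATS_KO. The largest fall by the fixed rule was that of Cebpe (chromosome 14, 54710360 to 54712174), which lies close to Lats2 (chromosome 14, 57689662 to 57758388). DNA of another strain carried along with an edited locus could lower nearby genes. With Cebpe, which prompted the window, left out, 6 of 323 tested genes within 20 Mb of Lats1 or Lats2 or 1.86% were called lower, against 119 of 12276 or 0.969% elsewhere (odds ratio 1.93, Fisher p = 0.14), which does not show an excess. Lrit1 (chromosome 14, 37054830 to 37064946), the next largest fall, lies on the same chromosome just beyond the window and counts as elsewhere, so the end of the window decides where it counts. Cebpe was also lower in YAP_OE, at 1.09 ± 0.640 CPM (SD, n = 5) against 9.59 ± 2.31 CPM (n = 4) in TdTomato, and so was Lrit1, at 2.49 ± 1.16 against 12.2 ± 3.64 CPM. These values were chosen after they were seen, and the labels of that group name no change at Lats2. Neighbouring genes are not independent and the labels do not name a strain for these libraries, so the hypothesis stays open.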
